A study of Canis lupus familiaris and Dasypus novemcinctus and Ornithorhynchus anatinus with 3 samples.

How the data were processed

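Messenger RNA sequencing libraries of pregnant endometrium were available for dog, armadillo and platypus, 1 library per species. Per the labels' protocols, RNA was extracted on columns with DNase treatment and libraries followed standard Illumina protocols. The submitters' processing notes name Bowtie, and the aligner version, genome builds and annotation release are not given in the sources used here. The stage of pregnancy and the number of animals are not given in the labels.

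For dog, the authors deposited estimated counts of reads per gene, per the file headers. These values equal the mapped bases divided by 34, so 516 of them are not whole, and they were rounded before use. The dog table also holds deposited scores, namely mapped bases and a relative abundance whose unit the header does not state. These were used only for checks. Read count divided by the relative abundance and by a fitted constant gave whole gene lengths, within 0.1 bases. This held for 100% of 5644 genes with more than 500 reads. The constant was chosen to make the lengths whole. Taken as a total of reads, it was 22083780, above the 13625465 reads summed over the listed genes. For armadillo and platypus the authors deposited raw counts of reads per gene, per the file headers. The armadillo table lists only genes with at least 1 read, so a gene missing from it is not taken as 0, while the dog and platypus tables list genes at 0 (4206 or 21.8% and 7828 or 42.4% of genes). The last line of the dog and of the armadillo table holds totals and no gene and was left out. No column of per-sample values was left unmapped. The counts are not corrected for gene length, so a fold between species also contains any difference in the length of the gene models.

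Genes were matched between species by upper-case symbol, using symbols that occur once in a table. Of 1347 dog genes named by sequence accession, 82 were given a symbol from the dog RefSeq gene table by exact accession. Genes with a UniProt entry name (1428 in dog, 54 in platypus), genes turned into dates by a spreadsheet (23 in dog, 17 in armadillo) and genes with no symbol were not matched. In dog, 8 symbols also occur as the first part of a UniProt entry name, and for 4 of them that second gene had more than 10 times the reads. In all, 12505 genes were matched in at least 2 tables and 6386 in all 3. Shifting the platypus counts by 1 line against their symbols lowered the Spearman correlation with dog over 9073 genes from 0.461 to 0.150 and 0.148, so names and counts were taken as aligned. The tables give no coordinates. The dog gene table, of assembly UU_Cfam_GSD_1.0, was used only for names and for the order of neighbouring genes, and its build may differ from that of the counts.

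Counts were divided by the total of the library, taken as the sum over its listed genes (13625465 reads in dog, 13218476 in armadillo and 2243556 in platypus), and scaled to give CPM. Normalised CPM was CPM times a median-of-ratios factor over 3496 genes at 2 CPM or more in all 3 libraries, which was 0.797 for dog, 0.997 for armadillo and 1.20 for platypus. Log2 folds used a pseudocount of 1 normalised CPM, which understates folds of low genes. A gene was counted as different where the fold on that scale was 4 or more and the higher library reached 5 normalised CPM. Genes at 2 CPM or more were called expressed. Folds of single genes in the text are ratios of normalised CPM without a pseudocount, with exact 95% intervals conditional on the total of both counts, and levels have exact Poisson 95% intervals. Intervals cover counting error only, because each species has 1 library. Reads without molecular identifiers are not independent molecules, so the intervals may be too narrow even for counting error. A count of 0 allows up to 3 reads, equal to 0.175 normalised CPM in dog, 0.226 in armadillo and 1.60 in platypus. With 1 library per species no p-value was computed.

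Before the data were examined, 24 gene lists, the comparisons, the limits and the rule for named genes were fixed. The lists covered progesterone response, hormone receptors, gland secretion, implantation signalling, prostaglandins, the IGF axis, immune tolerance, antigen presentation, leukocytes, epithelium, ciliated cells, stroma, smooth muscle, endothelium, trophoblast, yolk sac and liver-type proteins, red blood cells, ovarian steroid cells, calcium transport, nutrient transport, cell cycle, hypoxia, heat shock with immediate early genes, and housekeeping. For each list with 5 or more matched members the median log2 fold was placed among 10000 random lists of the same size matched on deciles of mean expression, as a description of these libraries. Of 72 list comparisons 65 had enough members. The limits of 2.5 and 97.5 for calling a percentile outside the central range were chosen after the values were seen. The rule named the 10 highest genes per library, the 10 largest folds per direction and pair, the 15 largest per direction for both eutherians against platypus, up to 4 members of each list and a set of fixed genes. Because the largest folds proved to be dominated by genes listed at 0, the 20 largest per direction and pair, and 25 for both eutherians, among genes at 2 CPM or more in every library compared were added after values were seen. Further members of the fixed and second lists, genes of the reverse presence class, DLX5, PRGR_CANFA, RELX_CANFA, HBB_CANFA, HBA_ORNAN, B2MG_ORNAN and ANXA2_CANFA were also named after their values were seen. Members of gene families such as keratins, collagens, actins and ribosomal proteins can share reads with close copies and their levels are uncertain to that extent. Some single genes are not reported here.

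Alternatives covered scaling (none, totals over matched genes, upper quartile), pseudocounts of 0.1 and 5, level limits, repeated symbols, genes at 0, the expression floor and the correlation method. Added later were a limit of 2 CPM in every library, matching of UniProt entry names, thinning to the platypus total, list members at 0 left out or set to 3 reads, and unlisted armadillo genes taken as low. The counting step was tested on simulated data: of 6386 genes, 100 of 100 with an 8-fold difference and 0 of 100 with a 2-fold difference were called, with no call among 6186 unchanged genes, in each of the 3 pairs. These simulated libraries held counting error only, so the result follows from the limits set. It checks the counting step and gives no rate of false calls between the species. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.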

Results

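Messenger RNA of the lining of the uterus (endometrium) was sequenced in pregnancy from dog and armadillo, which are placental mammals (eutherians), and from platypus, an egg-laying mammal. Each species was represented by 1 library, so every value is a single measurement and no difference has a replicate check. Intervals cover counting error only. The tables held 13625465 reads in 19290 dog genes, 13218476 reads in 12335 armadillo genes and 2243556 reads in 18481 platypus genes. Genes at or above 2 CPM (reads scaled to the library total) numbered 11241 in dog, 10050 in armadillo and 8486 in platypus. Levels are given as normalised CPM, and folds compare those levels between libraries.

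The 10 most abundant genes were listed for each library. Among those of the dog library, most of which had no usable symbol, were DSP (desmoplakin, a desmosome protein of epithelia; ENSCAFG00000009570) at 3988 normalised CPM, CTSZ (the lysosomal protease cathepsin Z) at 3506 and ACLY (ATP citrate lyase, an enzyme of lipid synthesis) at 2425. The armadillo library was led by FN1 (fibronectin; ENSDNOG00000000626) at 22005 normalised CPM and EEF1A1, a translation elongation factor, at 20994, and also held the smooth muscle genes TAGLN (10964) and MYH11 (10768), the intermediate filament gene VIM (10198) and the endothelial diaphragm gene PLVAP (7244). The platypus library was led by RCN2 (a calcium-binding protein of the endoplasmic reticulum; ENSOANG00000002100) at 23040.1 normalised CPM, with the protein disulfide isomerases PDIA3 (18404), PDIA4 (16584) and PDIA6 (14904) and the actin gene ACTA2 (13562) also among its 10 highest, beside the general cell genes EEF1A1 (16189), ACTB, EEF2, HSPA8 and GNB2L1. The 10 highest genes took 3.93% of reads in dog, 12.1% in armadillo and 12.1% in platypus.

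Dog and armadillo were compared to describe how the endometrium of these 2 eutherians differed. Epithelial genes were higher in dog, and 7 of 9 matched markers were at least 4-fold higher there. KRT7, a keratin of simple epithelia, stood at 1741 (95% interval 1722 to 1761) normalised CPM in dog and 536 (95% interval 524 to 549) in armadillo, a difference of 3.25-fold (95% interval 3.16 to 3.33) that lay below the 4-fold limit. The adhesion gene EPCAM was 17.4-fold (95% interval 14.3 to 21.4) higher in dog and ST14, a membrane serine protease of epithelia, 32.6-fold (95% interval 25.3 to 42.7) higher. Genes of the cell cycle were higher in dog in 8 of 11 cases, among them RRM2, a subunit of ribonucleotide reductase, at 44.2-fold (95% interval 37.8 to 52.0) and the mitotic kinase gene CDK1 at 13.3-fold (95% interval 11.3 to 15.7).

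Genes of muscle, vessels and matrix were higher in armadillo. All 6 matched smooth muscle markers were at least 4-fold higher there: MYH11, the smooth muscle myosin heavy chain, stood at 10768 normalised CPM against 1.29 in dog, and TAGLN (transgelin) was 633-fold (95% interval 565 to 712) higher. All 6 matched endothelial markers were also higher, including the junction gene ESAM at 53.8-fold (95% interval 45.5 to 64.1), as were all 5 matched stromal markers, including COL3A1 (type III collagen) at 17.8-fold (95% interval 17.4 to 18.2) and POSTN (periostin) at 180.5-fold (95% interval 143 to 231). Genes of the insulin-like growth factor (IGF) axis were higher in armadillo in 6 of 10 cases, led by the binding proteins IGFBP2 (9200.0 against 72.5 normalised CPM), IGFBP5 (2035 against 14.1) and IGFBP3 (788 against 5.73). IGFBP1, a secreted marker of decidual cells in primates, went the other way, at 301 in dog and 18.5 in armadillo. Immune tolerance and complement genes were higher in armadillo in 6 of 10 cases, including the galectin gene LGALS1 at 46.9-fold (95% interval 42.7 to 51.7) and the complement inhibitor SERPING1 at 22.9-fold (95% interval 21.5 to 24.5). IDO1, which degrades tryptophan, stood at 86.9 in armadillo and 0.643 in dog.

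Leukocyte markers were higher in armadillo in 6 of 12 cases, with the macrophage receptor gene CSF1R at 113 normalised CPM against 7.02. The T cell gene CD2 stood at 5.81 in armadillo and 0.292 (5 reads) in dog. Gland secretion genes were higher in armadillo in 3 of 5 cases, among them ENPP2, which encodes autotaxin, at 1802 against 0.819, and the prostaglandin synthase gene PTGS1 stood at 329 against 2.69. Nutrient transporters were higher in dog in 4 of 12 cases, including the glucose transporter gene SLC2A1 at 5.84-fold (95% interval 5.52 to 6.17) and the glutamate transporter gene SLC1A1 at 266 against 1.96. Hypoxia genes were mixed, with the kinase gene PDK1 higher in dog (22.3 against 2.19) and EPAS1 higher in armadillo (1233 against 138). None of the 8 matched housekeeping genes differed 4-fold.

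On the log2 scale, the median fold of dog over armadillo was 2.79 for epithelial markers, 2.80 for the cell cycle, 1.62 for hypoxia and angiogenesis and 1.01 for nutrient transport, at the 100th, 100th, 99.3th and 99.6th percentiles of 10000 random lists matched on expression. The median of armadillo over dog was 5.67 for smooth muscle, 5.38 for endothelium, 4.04 for immune tolerance, 3.97 for the IGF axis, 2.73 for stroma, 2.68 for gland secretion, 2.16 for leukocytes and 1.45 for ciliated cells, all at or above the 98.5th percentile. The bootstrap intervals over members included 0 for hypoxia, nutrient transport, the IGF axis, gland secretion and ciliated cells. For ciliated cells 0 of 5 members passed the 4-fold limit and 3 were listed at 0 in dog, and a second ciliary list, chosen after the data were seen, lay at the 71.9th percentile. The other lists lay within the central range of their random lists: heat shock and immediate early genes 2.11, trophoblast 1.37, progesterone response 0.76, calcium transport 0.52, antigen presentation 0.48, prostaglandin genes 0.38, housekeeping 0.05, implantation signalling -0.35 and hormone receptors -0.55, again armadillo over dog. Of 8908 genes matched between the 2 tables, 869 were at least 4-fold higher in dog and 1358 in armadillo, and the counts were 664 and 814 when both libraries had to reach 2 CPM. The excess for armadillo depended on scaling, with 1118 genes higher in dog and 1183 in armadillo without scaling, and 1263 and 1329 with totals over matched genes. Of the 1358, 95 were listed at 0 in dog, among them EEF2, TPT1, RPL7A and RPL11, which every cell uses, and dog ANXA2 had 6 reads under its symbol and 43787 under a second gene named ANXA2_CANFA. The armadillo table lists no gene at 0, so a gene without reads there could not be counted as higher in dog. With genes at 0 left out, the counts were 869 in dog and 1263 in armadillo.

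**Figure D1:**
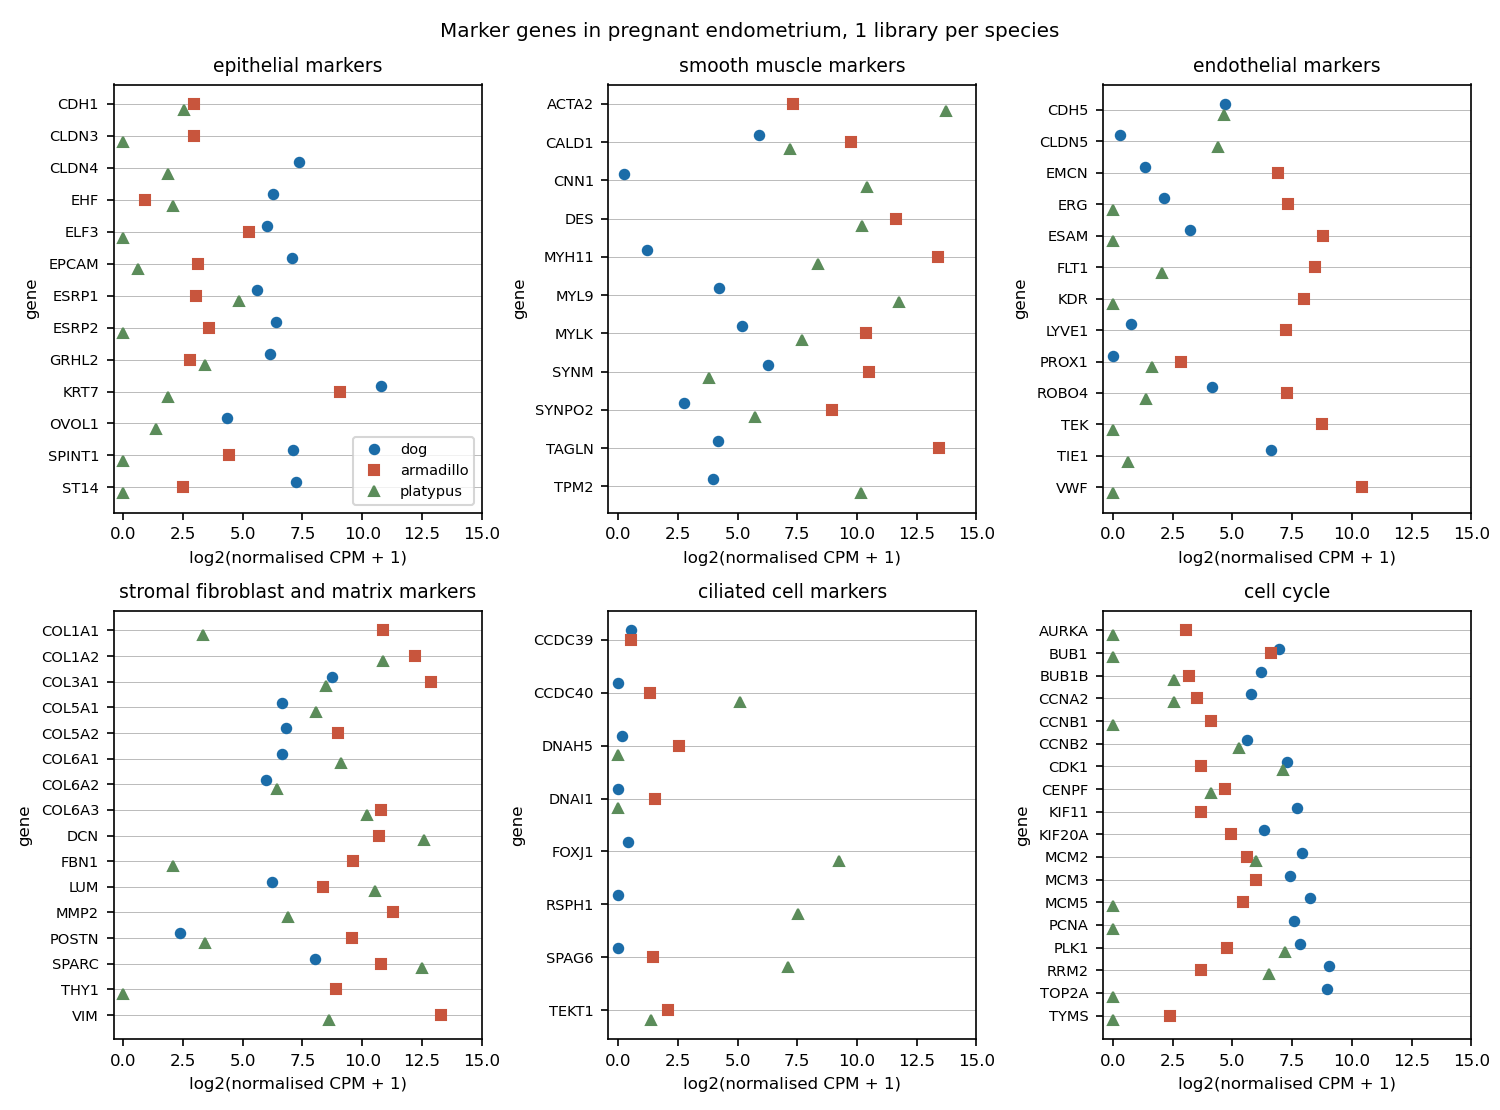
Levels of marker genes of 6 lists, as log2(normalised CPM + 1) on the horizontal axis, with 1 row per gene and 1 point per library (circle dog, square armadillo, triangle platypus; a missing point is a gene that was not matched in that table). Circles lie to the right of squares for most epithelial and cell cycle genes and to the left for smooth muscle, endothelial and stromal genes, and triangles at 0 are genes listed at 0 reads in platypus.

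Dog and platypus were compared as a eutherian and an egg-laying mammal. Epithelial markers were higher in dog in 10 of 11 cases, with KRT7 at 1741 normalised CPM against 2.67 (5 reads) in platypus. Among the nutrient transporters, 7 of 11 were higher in dog, including SLC2A1 at 51.0-fold (95% interval 33.9 to 80.4), whereas SLC1A1 was 16.8-fold (95% interval 16.2 to 17.4) higher in platypus. Among cell cycle genes 7 of 11 were higher in dog, with RRM2 at 5.77-fold (95% interval 4.96 to 6.74), and CDK1 was similar (156 and 137). In platypus 4 of these 11 cell cycle genes and 3 of the 11 nutrient transporters were listed at 0. The lipid synthesis gene ACLY (2425 against 19.3) and F3, which encodes tissue factor (326 against 2.67), were also among the genes with the largest folds.

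Most smooth muscle markers fixed beforehand and several ciliary genes were higher in platypus than in dog. Of the smooth muscle markers 6 of 8 were higher in platypus, among them CNN1 (calponin) at 1378 normalised CPM against 0.175 (3 reads) and MYL9 at 194-fold (95% interval 173 to 219). A second list of smooth muscle genes, chosen after the data were seen, did not stand apart: its median log2 fold of dog over platypus was 0.16, at the 49.1th percentile of random lists, with 5 of 19 members higher in dog and 4 in platypus. Of the ciliated cell markers 4 of 6 were higher in platypus: FOXJ1, the transcription factor of motile cilia, stood at 598 (95% interval 563 to 634) against 0.351 (95% interval 0.129 to 0.764) in dog, and RSPH1 (185), SPAG6 (137) and CCDC40 (33.7) were listed at 0 in dog. ESR1, the oestrogen receptor, was 175-fold (95% interval 145 to 214) higher in platypus, MSX1, a homeobox transcription factor, 307-fold (95% interval 227 to 426) and RCN2 566-fold (95% interval 525 to 611). AGR2, a disulfide isomerase of secretory epithelia (1539.5 against 6.02), DERL3, a component of endoplasmic reticulum degradation (1051 against 8.36), and IGHM, an immunoglobulin heavy chain (1473 against 10.2), were also higher in platypus.

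The median log2 fold of dog over platypus was 6.02 for epithelial markers (4.19 without the 4 members listed at 0 in platypus and 5.68 with these set to 3 reads), 3.24 for the cell cycle (1.94 and 3.49) and 2.66 for nutrient transport (2.50 and 2.47), each at or above the 99.8th percentile of its random lists. The median of platypus over dog was 4.57 for smooth muscle and 6.12 for ciliated cells, both at the 100th percentile. Of the 6 ciliated cell markers 4 were listed at 0 in dog and 2 in platypus, so that only FOXJ1 was left without zeros, and the bootstrap interval of the median (-0.08 to 8.17) included 0. The remaining lists lay within the central range, including yolk sac and liver-type proteins (median 0.00, 5 matched members, all listed at 0 in platypus and 4 also in dog, so that zeros were compared with zeros) and ovarian steroid cell markers (median 0.00). Of 9073 matched genes, 2474 were at least 4-fold higher in dog and 1221 in platypus, and 1137 of the 2474 were listed at 0 in platypus. With genes at 0 left out the count for dog was 1337, and with 2 CPM required in both libraries the counts were 855 and 783.

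Armadillo and platypus were compared in the same way. Vessel and matrix genes were higher in armadillo: 7 of 8 endothelial markers passed the 4-fold limit, with FLT1, a receptor for vascular endothelial growth factor, at 349 normalised CPM against 3.21, and VWF at 1359, listed at 0 in platypus. Of the stromal markers 7 of 12 were higher in armadillo, including COL1A1 at 208-fold (95% interval 129.7 to 357), FBN1 (fibrillin) at 247-fold (95% interval 114 to 674) and VIM at 26.3-fold (95% interval 24.4 to 28.3), whereas LUM (lumican) was 4.52-fold (95% interval 4.31 to 4.75) and DCN (decorin) 3.68-fold (95% interval 3.60 to 3.77) higher in platypus. Smooth muscle markers were higher in armadillo in 5 of 7 cases, with MYH11 at 32.4-fold (95% interval 30.0 to 35.1) and SYNM at 112-fold (95% interval 74.9 to 174), but ACTA2 was 84.3-fold (95% interval 80.7 to 88.2) higher in platypus. IGF axis genes were higher in armadillo in 6 of 9 cases, with IGFBP5 at 211-fold (95% interval 134 to 357) and IGFBP3 at 18.6-fold (95% interval 14.9 to 23.6). Genes higher in platypus included SLC1A1 at 4466 against 1.96, PDK1, a kinase of pyruvate dehydrogenase, at 393-fold (95% interval 273 to 589), and the ciliary gene SPAG6 at 79.3-fold (95% interval 51.7 to 127).

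The median log2 fold of armadillo over platypus was 7.67 for endothelium (5.89 over the 3 members not listed at 0 and 7.04 with zeros set to 3 reads), 4.41 for stroma, 3.99 for immune tolerance (4.10 and 3.24), 3.30 for hypoxia and angiogenesis (0.94 and 2.85), 2.69 for the IGF axis (2.37 and 2.79) and 2.68 for smooth muscle, each between the 99.46th and 100th percentiles. The bootstrap interval of stroma included 0. Without zeros the hypoxia list was at the 82.2th percentile, within the central range. Ciliated cell markers had a median of 0.70, at the 25.6th percentile, with 2 of 5 members higher in platypus. The lists of heat shock and immediate early genes (7.96; 1.08 without zeros) and antigen presentation (6.23; -1.92 without zeros) lay at the 99.9th and 100th percentiles with 3 members each at 0 in platypus and bootstrap intervals that included 0, and HSPA8, CALR and PDIA3 were higher in platypus. Red blood cell markers had a median of 2.23 with all 5 matched members listed at 0 in platypus, and lay within the central range together with the other lists. A haemoglobin gene was nevertheless present in platypus under the entry name HBA_ORNAN, at 172 normalised CPM (95% interval 154 to 192). Of 7296 matched genes, 2484 were at least 4-fold higher in armadillo, 1148 of them listed at 0 in platypus, and 963 were higher in platypus. Genes without reads in armadillo are not in its table, so they could not be counted as higher in platypus. Without genes at 0 the counts were 1336 and 963, and with 2 CPM required in both libraries 842 and 759.

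**Figure D2:**
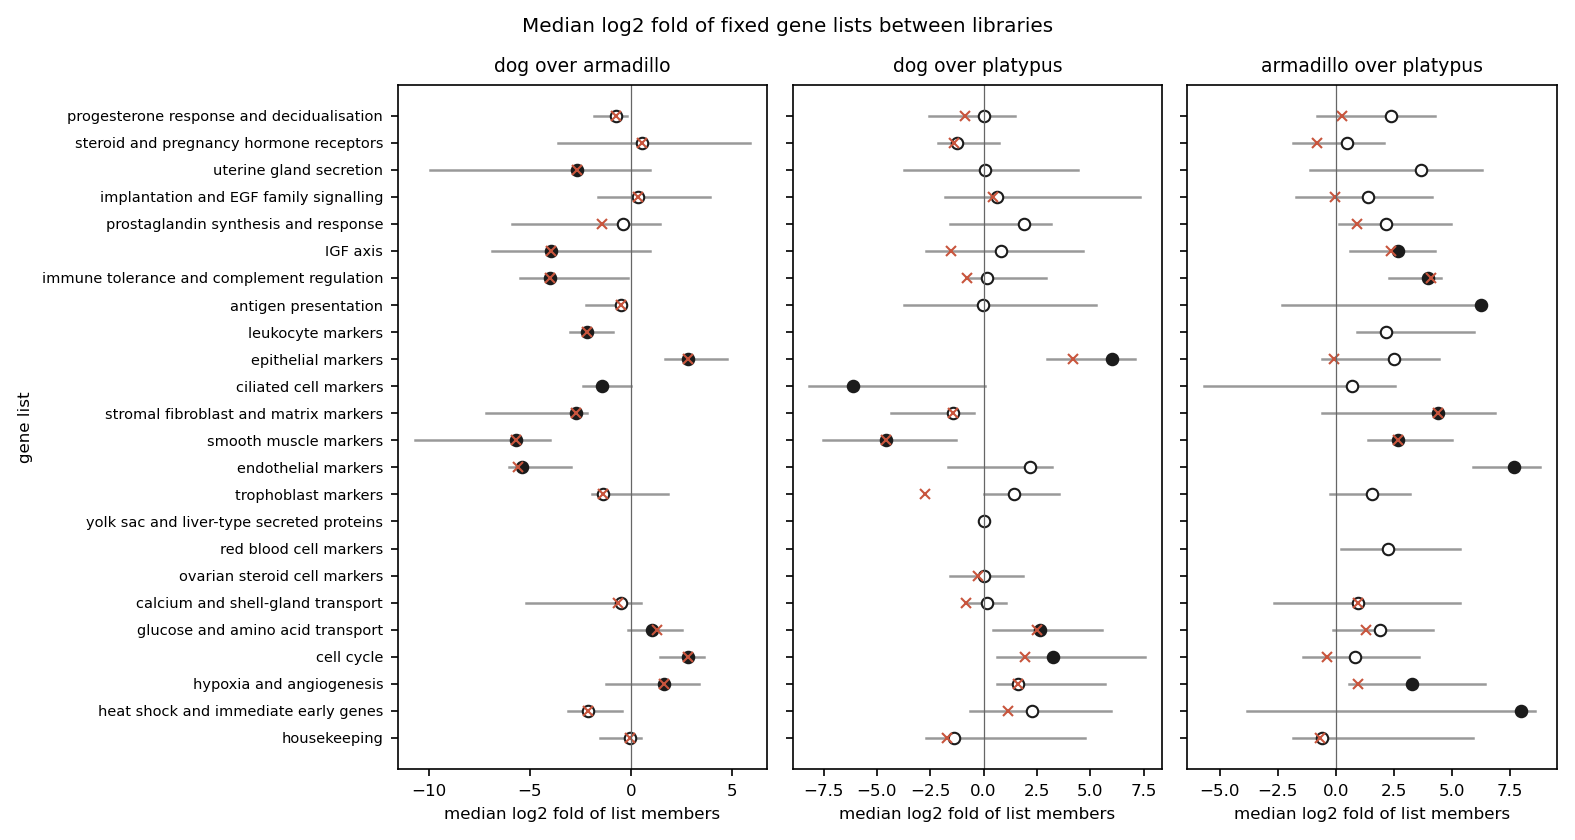
Median log2 fold of the members of each gene list fixed beforehand, for dog over armadillo, dog over platypus and armadillo over platypus, with circles for medians, filled where the median lay outside the central 95% of 10000 random lists, grey lines for bootstrap 95% intervals over the members of a list, and crosses for medians without members listed at 0 (shown for 5 or more members). Across the 3 panels 25 of 65 medians are filled, where random lists would give 3.25 on average. The limits were chosen after the values were seen, the panels share libraries, and genes of a list may vary together. The value of 3.25 is therefore a description of random lists and not a test of these medians.

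Both eutherians were set against platypus to find genes that differed from the egg-laying species in the same direction. Genes lower in both eutherians and higher in platypus included RCN2 (23040.1 normalised CPM, against 40.7 in dog and 75.2 in armadillo), MSX1 (772, 2.52 and 2.41), S100A13 (5339, 19.7 and 125), AGR2 (1539.5, 6.02 and 1 read), DERL3 (1051, 8.36 and 1.36), IQGAP2 (920.1, 4.04 and 8.82) and DIO2, the enzyme that activates thyroid hormone (106, 2.81 and 2.49). Among genes detected in all 3 libraries, those higher in both eutherians included KRT7, the basement membrane gene LAMB1 (536 in dog, 1479 in armadillo and 9.63 in platypus), FBLN1 (205, 2824 and 3.21) and NRP2, a neuropilin (263, 434 and 6.42). General cell genes stood beside them, such as UBA1 (645, 892 and 5.88) and the proteasome gene PSMD2 (593, 876 and 14.4). The largest folds by the rule fixed beforehand, led by RPS15, RPS25, COPA and RPS7, were of genes listed at 0 in platypus, and no fold is given for them.

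Of the 6386 genes matched in all 3 tables, 1463 were at least 4-fold higher in both eutherians and 474 lower in both, and 751 (51.3%) of the 1463 were listed at 0 in platypus. Independent lists of the same sizes would share 657 and 118 genes, and libraries simulated with counting error alone, with 1 platypus library in both comparisons, shared on average 0.02 and 0. That simulation holds no variation between animals, so it does not show how many genes would pass without a species difference. The platypus library enters both comparisons, so part of the excess may come from it. With upper-quartile scaling the counts were 1269 and 675, so that 65.3% of the genes were higher in the eutherians instead of 75.5%. Leaving out genes at 0 gave 712 higher and 437 lower, and requiring 2 CPM in all 3 libraries gave 405 higher and 326 lower. Genes without reads in armadillo are not in its table, so they could not be counted among the 474 lower in both eutherians.

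Presence and absence were compared to ask which genes were expressed in the eutherian endometria and not in that of platypus. Genes at 2 CPM or more in dog and armadillo and below 0.5 CPM in platypus numbered 1114 of 6386, of which 941 were listed at 0 and 173 had 1 read. They included RPS15, RPS25, COPA and PSMB4, which every cell uses, so a listing at 0 is not reported here as absence. A count of 0 allowed up to 3 reads, or 1.34 CPM in platypus, against 0.220 CPM in dog. The reverse class, at 2 CPM or more in platypus and below 0.5 CPM in both eutherians, held 52 genes. It included the homeobox gene DLX3 (20.9 normalised CPM in platypus), the growth factor gene FGF10 (7.49) and the ciliary genes DNAH12 (55.6) and ENKUR (25.1). A further 170 genes fell in this class if armadillo genes that its table does not list are taken as low.

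Genes of the progesterone response and of decidualisation, the change of stromal cells in pregnancy, were named beforehand, except PRGR_CANFA, named after its value was seen. The progesterone receptor gene PGR had 349 normalised CPM (653 reads) in platypus, and the dog gene PRGR_CANFA, the protein database name of the same receptor, had 13.0 (95% interval 11.4 to 14.9). FOXO1 was similar in all 3 libraries, at 52.6 (95% interval 49.2 to 56.1) in dog, 61.1 (95% interval 56.9 to 65.4) in armadillo and 49.7 (95% interval 40.2 to 60.9) in platypus. HOXA10 stood at 14.3 in armadillo and 36.9 in platypus, HOXA11 at 9.18 in dog, and HAND2 at 19.7 in dog and 3.62 in armadillo. IGFBP1 was listed at 0 in platypus, PRL was listed at 0 in dog and platypus, and CEBPB was not matched in any table. Over the whole list the median log2 fold was 0.00 for dog over platypus (-0.89 without zeros), which is the value of PRL, and 2.37 for armadillo over platypus (0.27 without zeros), both within the central range.

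Across the 6386 shared genes the Spearman correlation of levels was 0.607 between dog and armadillo, 0.394 between dog and platypus and 0.380 between armadillo and platypus. Pearson correlations of log2(normalised CPM + 1) were 0.613, 0.413 and 0.403. In the 3496 genes detected at 2 CPM in all 3 libraries the Spearman values were 0.492, 0.300 and 0.274. These are correlations across genes, which are not independent replicates, and they describe these 3 libraries.

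**Figure D3:**
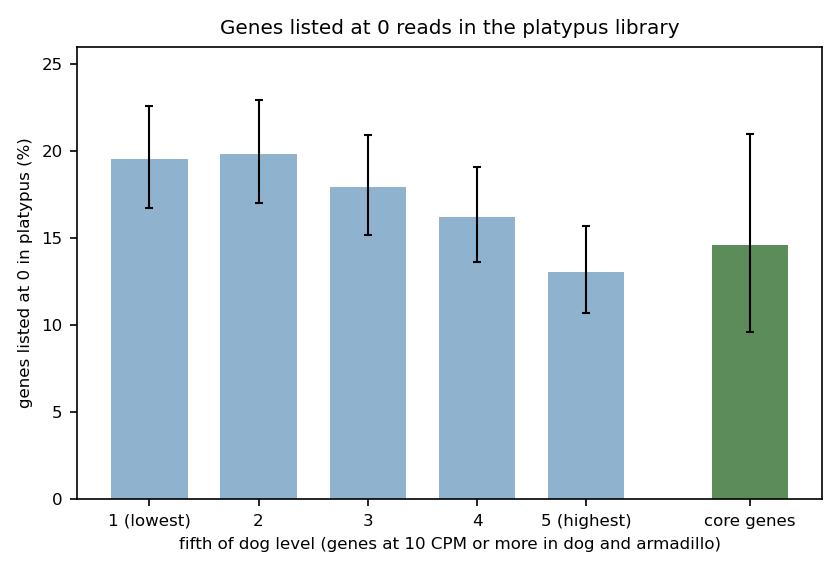
Share of genes listed at 0 reads in the platypus library, in percent, with exact 95% intervals, for the 3637 genes at 10 CPM or more in dog and armadillo in 5 groups of rising dog level and for 164 core genes that every cell uses, at any level. The share was 19.5% in the group with the lowest dog level, 13.0% in the highest and 14.6% in core genes.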

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

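The tests of genes listed at 0 in platypus were chosen only after the result was seen.

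Some genes outside the comparisons stood above what a count of 0 allows. Genes without a usable symbol held 21.1% of reads in dog, 10.2% in armadillo and 24.03% in platypus. In dog these included PRGR_CANFA, the entry name of the progesterone receptor, at 13.0 normalised CPM (223 reads), and RELX_CANFA, the entry name of relaxin, a hormone of pregnancy in dog, at 51.6 normalised CPM (95% interval 48.2 to 55.1; 882 reads). HBB_CANFA, the entry name of a haemoglobin, had 0.643 normalised CPM (11 reads). All 3 lay above the 0.175 normalised CPM that 0 reads would allow in dog, as any gene with more than 3 reads must. HBB_CANFA, at 0.807 CPM, lay below the 2 CPM set for expressed genes. In platypus HBA_ORNAN, another haemoglobin, had 172 normalised CPM (322 reads), above the 1.60 allowed there. The platypus entry B2MG_ORNAN had 1 read, or 0.535 normalised CPM, below that limit.

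Many genes expressed in both eutherians were listed at 0 in platypus. Of 3637 genes at 10 CPM or more in dog and armadillo, 630 (17.3%, exact 95% interval 16.1 to 18.6) were listed at 0, and the share was still 13.0% (10.7 to 15.7) in the 1 of 5 groups with the highest dog level, which argues against a shallow library as the whole cause. The share beside a neighbour at 0 along the dog gene order was 1.05 times that of all genes (17.8% against 17.0%, with 14.1 to 19.9 in 1000 permutations), which argues against a missing stretch of genome, as far as dog gene order stands for that of platypus. Genes that every cell uses, such as those of the ribosome, proteasome and respiratory chain, were at 0 in 24 of 164 cases (14.6%, 9.61 to 21.0), so platypus gene models that collected no reads may account for much of the pattern. Whether some of the genes are not used in platypus endometrium stays open. Within the 3637 genes, 614 of 3537 other genes (17.4%) and 16 of 100 core genes (16%) were at 0. The difference was only 1.36 percentage points, with an interval of -5.93 to 8.65 points.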

How the results depend on the processing

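The limit of 2 CPM in every library, the taking of unlisted armadillo genes as low, and the handling of list members at 0 were chosen after the data were seen. Of 116 values of counts and correlations under alternatives, 99 stayed within the limits set for them and 17 moved. With 2 CPM required in every library compared, genes higher in armadillo than dog numbered 814, genes higher in dog than platypus 855, genes higher in platypus than dog 783, genes higher in armadillo than platypus 842 (759 in platypus) and genes higher in both eutherians than platypus 405. With genes at 0 left out, genes higher in dog than platypus numbered 1337, genes higher in armadillo than platypus 1336 and genes higher in both eutherians than platypus 712. These filters leave fewer genes to count. The last count was 925 with a pseudocount of 5 and 954 with a level of 20. The genes in platypus, not dog or armadillo, numbered 33 with a floor of 5 CPM, 131 with the low libraries below 2 CPM, 222 with unlisted armadillo genes taken as low, and 0 with the low libraries at exactly 0, since the armadillo table lists no gene at 0. In genes at 2 CPM or more in all 3 libraries the correlations were 0.492, 0.300 and 0.274. Of 386 list medians 364 stayed within their bootstrap spread and 21 moved. Some of these spreads were wide, such as -9.95 to 0.92 for gland secretion, dog over armadillo, so staying within them is a weak criterion. The list median of antigen presentation, armadillo over platypus, reversed to -1.92 without members at 0, which leaves 4 members. Several medians within the central range also changed sign without members at 0. Trophoblast, dog over platypus, went from 1.43 to -2.74, and the IGF axis, dog over platypus, from 0.79 to -1.54. For armadillo over platypus, ciliated cells went from 0.70 to -3.79 and the cell cycle from 0.82 to -0.37. Of 1092 folds of named genes 999 moved by less than 1 on the log2 scale, 93 moved more and 0 reversed. Many of these genes were named for their large folds, so few reversals were possible. Relative to the scaling used, the median log2 fold of all genes shifted by 0.21 (dog over armadillo), 0.36 (dog over platypus) and 0.18 (armadillo over platypus) without scaling, and by 0.06, -0.17 and -0.33 with upper-quartile scaling. With totals over matched genes the shifts were 0.27, 0.52 and 0.31. Platypus depth limits detection there to about 1.34 CPM. Where values moved for reasons other than fewer genes the cause was not tested. No library could be left out, since each species has 1. No paired analysis was possible because no result comes from a test of replicates.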

Other observations

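The test of muscle, the test of epithelial share and the test of dynein genes were chosen only after the result was seen, as was the choice of the 3 second gene lists. The predictions for ciliated cells and for scaling were also written after that pattern was seen, but before their tests were run.

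Genes of protein folding and secretion in the endoplasmic reticulum were in part high in platypus. A second list of 52 such genes, none of them in the lists fixed beforehand, had a median log2 fold of platypus over dog of 2.04 (22 matched members) and of platypus over armadillo of 2.18 (27 members), both at the 99.9th percentile of random lists. SSR4, a subunit of the translocon-associated complex, stood at 3596 normalised CPM in platypus, 324 in dog and 279 in armadillo. LMAN1, a cargo receptor, stood at 866, 118 and 53.9, and XBP1, a transcription factor of secretory cells, at 880.5 in platypus and 109.9 in dog. At least 4-fold higher in platypus were 11 of 22 members against dog and 14 of 27 against armadillo, while 3 and 4 members were higher in the eutherian. These were P4HB, at 27.3 in platypus against 1319.7 and 1246, CREB3L1 and SEC24D in both comparisons and SSR1 against armadillo. CREB3L1 and SEC24D were listed at 0 in platypus. Between dog and armadillo the list did not stand apart (median of armadillo over dog 0.15).

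The homeobox gene DLX5, a member of the trophoblast list, stood at 221 normalised CPM in dog and 3.85 in armadillo, while TFAP2C of the same list stood at 1.70 and 45.0. BCAT1, an aminotransferase of branched-chain amino acids, had 2082 normalised CPM in dog, 1 read in armadillo and was listed at 0 in platypus.

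The medians of muscle, vessel, stromal and leukocyte markers were all higher in armadillo than in dog. A second list of smooth muscle genes, none of them in a list fixed beforehand, had a median log2 fold of armadillo over dog of 3.83 (17 of 20 members at least 4-fold higher), at the 100th percentile, and 3.73 at the same percentile without FLNC and CSRP1, whose levels had been seen. Abundant muscle genes of armadillo were TAGLN at 10964, MYH11 at 10768 and DES at 3150.2 normalised CPM, so RNA of the muscle wall of the uterus may be part of that library, although 17 of the 20 genes were also expressed in dog and muscle of vessels was not told apart. Against platypus, armadillo was also higher in the fixed and the second list (medians 2.68 and 2.23). The fixed list was higher in platypus than in dog as well (median 4.57), while the second list was not (dog over platypus 0.16). For a larger epithelial share in the dog library, the bootstrap intervals of all these lists had been predicted to overlap. The smooth muscle median exceeded the stromal one by 2.94 log2 units, but their intervals overlapped (4.02 to 10.7 and 2.16 to 7.19). The leukocyte interval (0.92 to 3.002) lay below that of smooth muscle, so the prediction was not met in full, although many leukocyte markers had few reads in dog. As a part of the difference, epithelial share cannot be told apart from muscle wall. Species and stage of pregnancy stay open and were not tested.

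Some genes of motile cilia were higher in platypus: DNAH10 stood at 197 normalised CPM in platypus, 5.97 in dog and 1.73 in armadillo, and WDR66 at 123, 1.23 and 4.37. In a second ciliary list the median of platypus over dog was 1.32 (2.46 without members at 0; 13 of 39 members at least 4-fold higher and 1 lower; 21 expressed in platypus and 10 in dog), and over armadillo 0.41 (1.96 without members at 0; 10 of 30 higher and 4 lower; 15 expressed in platypus and 16 in armadillo). Both medians lay at the 100th percentile of random lists, so ciliated cells of the uterine lining or of the oviduct may be more abundant in the platypus library, but both bootstrap intervals (-2.46 to 0.08 for dog over platypus and -1.96 to 0.69 for armadillo over platypus) included 0. Without the dynein genes the lower of the 2 percentiles was still 100, which argues against reads shared between dynein paralogs, a test added once a planned test of scaling had come out undecided. In that planned test the medians without scaling were 0.95 and 0.18, between the bounds of 0 and 1 set for it, so scaling stays open as part of the difference, and a species difference in the use of cilia was not tested.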
